A study of Mus musculus with 583 samples.

How the data were processed

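J1 mouse embryonic stem cells in 2i/LIF were profiled with 6 single-cell RNA-seq methods, and the files hold 1 table of counts for 38924 mouse genes and 92 ERCC spike-ins in 583 cells. For Drop-seq, SCRB-seq, CEL-seq2 and MARS-seq the authors deposited UMI counts per gene and cell, made with the Drop-seq pipeline per the submitters' processing notes. Per the same notes, reads were tagged with cell barcode and UMI, mapped with STAR 2.4.0 at its default settings and tagged with the genes whose exons they met. The submitters' processing notes add that only barcodes taken into consideration were kept, without the rule behind that choice. For Smart-seq / C1 and Smart-seq2 the authors deposited whole-number counts, taken here as read counts because these protocols carry no UMI. Per the labels, bcl2fastq and STAR 2.4.0 with the mm10 genome were used for every cell. What counted the Smart-seq reads, the annotation, the read length and any reduction of reads to a common number are given in none of these sources. Every deposited value was a whole number.

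All columns were mapped to a cell, and the cells of each method and replicate letter form a library. The library is the unit of replication (12 libraries, 2 per method), because cells of 1 library are not replicates. Of the gene identifiers, 37607 matched GENCODE M21 (GRCm38, the assembly also called mm10), which gave symbols, coordinates and lengths. The other 1317 held 0.297% of the counts of mouse genes and stayed in, under their identifiers. 12305 genes had no count in any cell. No cell was left out, and no doublet caller was run. 10 cells held more than 2 times the median count of their library.

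Values per cell were genes with at least 1 count, from all counts and after thinning each cell without replacement to 10000 counts, the shares of counts from mitochondrial, ribosomal protein and spike-in genes, and the share of the naive and core list seen in thinned cells. Each library was given its median over cells, or its mean for that list. Extra-Poisson variation was the library median of log2 of the variance less the mean over the squared mean, for genes with a mean of at least 1 count in every library. These values and the Spearman correlation of replicates were tested by an exact one-sided permutation over all 10395 divisions of 12 libraries into 6 pairs, with Benjamini-Hochberg adjustment over 8 tests. The smallest p this allows is 9.62e-05. A permutation within 2 against 2 libraries cannot go below 0.333, and no pair of methods was tested on such values. Shares of cells carry exact Clopper-Pearson intervals at 95%.

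Expression was compared on counts summed over the cells of each library, with edgeR 4.0.16. Genes were kept by filterByExpr with method as the group (14293 of 26619 with a count), scaled by TMM and fitted with a robust quasi-likelihood model holding 1 mean per method. The 12 libraries shared 1 estimate of the spread (common biological coefficient of variation 0.418, 6 residual degrees of freedom, median prior degrees of freedom 11.9). There were 5 orthogonal contrasts and the difference of the 2 C1 contrasts, each with Benjamini-Hochberg adjustment over its genes, and genes passed at an adjusted p below 0.05. Fold changes are on the log2 scale and average methods there. Group values are means of TMM-scaled CPM over libraries. Where all libraries of a side were at 0, the fold is a lower bound from a floor of 3 counts over that side. Across all methods, 9354 genes (65.4%) differed in the joint test of the 5 orthogonal contrasts.

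Gene lists, 26 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over 156 tests. Camera with an estimated correlation called none of them, with a lowest adjusted p of 0.276, against 36 calls with the preset one. A list gene that passed the gene-wise test is said to have risen or fallen. The counts adjusted over the list alone use only that list's genes. Variation among cells was tested with limma on each gene's residual log2 squared coefficient of variation above a loess trend on the mean (span 0.5) in thinned cells, with 1 mean per method and their average as the contrast, for genes with a mean of at least 0.2 counts in every library.

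Genes were named by a rule fixed before the data were examined. Per contrast these were the 5 largest rises and 5 largest falls among genes that passed with an average log2 CPM of at least 5 and libraries that did not overlap. From each list discussed came the 2 genes with the smallest p and the 1 with the highest expression. Pou5f1, Sox2, Nanog, Zfp42, Esrrb and Klf4 were always named, and so were the 15 most variable genes. The same rule was applied to the C1 difference. Some genes that it selected are not reported here. Xist, the Zscan4 genes and the cells counted for Egr1 and Slc34a2 were chosen after their values were seen.

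Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 Wald test (1.42.0), no filter, a replicate block, thinned cells, glmTreat against a 2-fold change, limma on the mean over cells of log2 CPM plus 1, removal of a loess trend on transcript length (span 0.75), fry, other thinning depths, summaries and minimums, and each library left out in turn. Added after seeing the data were protein-coding genes without ribosomal protein, histone, mitochondrial and Gm genes, genes with 10 counts in every library, and Drop-seq barcodes 1 base apart joined. A library left without its partner is assumed to vary like the others. The share of a gene's 31-mers that occur in another gene was computed from GENCODE M21 transcripts. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statmod 1.5.0 were used.

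The tests were first run on simulated data, in which 200 of 14293 genes were changed in equal numbers by 8, 4, 2 and 1.5 fold. The edgeR test recovered 84, 66, 20 and 0% of these in full-length against 3' tag methods, 42, 26, 0 and 2% in Smart-seq / C1 against Smart-seq2, 70, 48, 12 and 0% in in vitro transcription against PCR tag methods, 44, 20, 0 and 0% in CEL-seq2 against MARS-seq, 46, 22, 0 and 0% in Drop-seq against SCRB-seq and 32, 2, 0 and 0% in the C1 difference. At most 8 unchanged genes were called in any of them. Camera called a list raised 1.5-fold in full-length against 3' tag methods over 14293 genes (adjusted p = 1.09e-23, adjusted p = 0.000252 with an estimated correlation) and 0 other lists. Genes were drawn independently of each other there, so this cannot tell whether the preset correlation suits the real data. The test of variable genes recovered 121 of 169 genes (71.6%) among 2276, with 1 unchanged gene called.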

Results

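Cells of the J1 line, a mouse embryonic stem cell line, had been grown in 2i/LIF medium, in which LIF and inhibitors of MEK and GSK3 hold such cells in the naive state of pluripotency. Their RNA was profiled with 6 single-cell methods, each in replicate libraries A and B, so that 12 libraries held 583 cells. The comparisons ask how the same kind of cell looks through each method. Smart-seq / C1 and Smart-seq2 copy transcripts along their length and were counted as reads. CEL-seq2, MARS-seq, SCRB-seq and Drop-seq tag the 3' end of each transcript and were counted as unique molecular identifiers (UMIs), so reads and UMIs do not count the same molecules. CEL-seq2 and MARS-seq amplify by in vitro transcription and the other 4 methods by PCR. Smart-seq / C1 and CEL-seq2 cells were captured on the Fluidigm C1 chip, SCRB-seq cells were sorted by FACS and Drop-seq cells were caught in droplets.

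Replicates A and B held 69 and 61 cells for Smart-seq / C1, 80 and 77 for Smart-seq2, 34 and 37 for CEL-seq2, 29 and 36 for MARS-seq and 39 and 45 for SCRB-seq, and 42 and 34 barcodes for Drop-seq. The median total count per cell in A and B was 318324 and 323536 reads in Smart-seq / C1 and 493394 and 475631 in Smart-seq2. It was 36952 and 76839 UMIs in CEL-seq2, 24554 and 27148 in MARS-seq, 53232 and 48366 in SCRB-seq and 18886 and 16192 in Drop-seq. Summed over cells, mouse genes received 18533395 and 17630767 counts in Smart-seq / C1, 34984056 and 32104987 in Smart-seq2, 1236129 and 2784441 in CEL-seq2, 666278 and 953037 in MARS-seq, 2283008 and 2156307 in SCRB-seq and 922703 and 583302 in Drop-seq. Intervals and floors given below cover counting error only. Replicates are not said to come from separate cultures, so each p-value measures the spread between these libraries, which may be technical.

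The first comparison asks how many genes each method saw in a cell. The mean of the library medians was 7484 ± 200.1 in Smart-seq / C1, 9088 ± 10.6 in Smart-seq2, 7544 ± 1115 in CEL-seq2, 4769.8 ± 292 in MARS-seq, 7938 ± 153 in SCRB-seq and 4838 ± 324 in Drop-seq genes per cell (± SD, n = 2 libraries each). The methods differed beyond the spread of their replicates (exact permutation p = 0.00471, adjusted 0.00943, with 95.4% of the sum of squares between methods). With every cell thinned to 10000 counts the values lay closer together: 3224 ± 219.9 in Smart-seq / C1, 3769.5 ± 94.05 in Smart-seq2, 3667 ± 9.55 in CEL-seq2, 3126 ± 104 in MARS-seq, 3806 ± 33.2 in SCRB-seq and 3615 ± 42.8 in Drop-seq genes. The difference between methods remained (exact permutation p = 0.0107, adjusted 0.0171, with 92.1% of the sum of squares between methods). No cell had fewer than 10186 counts, so none was left out at this depth. In Drop-seq A, 29 of 42 barcodes lay 1 base from another barcode of the library, and in B 12 of 34. With such barcodes joined, the median of genes per cell was 6819 in A and 4830 in B from all counts, and 3616 and 3652 at 10000 counts.

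**Figure D1:**
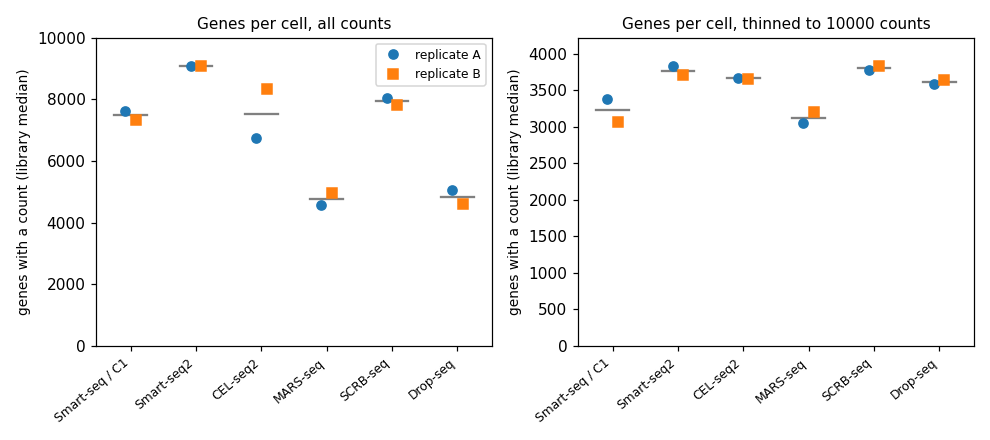
Genes detected per cell (y axis, number of genes) in each library, by method (x axis), from all counts on the left and from cells thinned to 10000 counts on the right; points are library medians, coloured by replicate, and grey lines their mean. At 10000 counts the method means lie between 3126 and 3806 genes.

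Expression profiles of whole libraries ranked genes more alike within methods than between them on average. Across 26619 genes, the Spearman correlation of summed counts between replicates averaged 0.904 (range 0.879 to 0.952), and between libraries of different methods 0.799 (range 0.707 to 0.898). Genes are not independent replicates, so the libraries were permuted (one-sided exact permutation p = 9.62e-05, the smallest the 10395 divisions can give, adjusted 0.00077). Smart-seq / C1 A correlated less with B (0.879) than with Smart-seq2 A (0.898) and B (0.895), but over genes of at least 10 CPM it correlated more with B (0.909 against 0.836 and 0.833). The closest pair of methods was Smart-seq / C1 with Smart-seq2 (mean 0.886), followed by SCRB-seq with Drop-seq (0.872).

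Ribosomal protein genes, which encode the protein parts of the cytosolic ribosome, took shares of the counts that followed the method. The median cell gave them 2.22 ± 0.616 in Smart-seq / C1, 3.09 ± 0.295 in Smart-seq2, 6.63 ± 1.24 in CEL-seq2, 13.1 ± 0.521 in MARS-seq, 8.70 ± 0.617 in SCRB-seq and 8.97 ± 0.317 in Drop-seq percent of endogenous counts (± SD, n = 2). The methods differed (exact permutation p = 0.000289, adjusted 0.00115, with 98.3% of the sum of squares between methods). The mitochondrial share of counts, from transcripts of the mitochondrial genome, was 5.13 ± 0.791 in Smart-seq / C1, 2.81 ± 0.0496 in Smart-seq2, 9.49 ± 0.128 in CEL-seq2, 3.35 ± 3.63 in MARS-seq, 5.35 ± 0.605 in SCRB-seq and 1.97 ± 0.402 in Drop-seq percent. The methods differed here too (exact permutation p = 0.0289, adjusted 0.033, with 83.6% of the sum of squares between methods). MARS-seq A and B were far apart here, at 5.91% and 0.782%. The unadjusted exact permutation p was 0.00077 without MARS-seq A and 0.00173 without MARS-seq B. Without any other single library it passed the threshold no longer: 0.0562 without Smart-seq / C1 A, 0.0506 without Smart-seq / C1 B, 0.0511 without Smart-seq2 A, 0.0514 without Smart-seq2 B, 0.0848 without CEL-seq2 A, 0.0961 without CEL-seq2 B, 0.0536 without SCRB-seq A, 0.0581 without SCRB-seq B, 0.0525 without Drop-seq A and 0.0614 without Drop-seq B. ERCC spike-ins, synthetic RNAs added in known amounts, took 8.82 ± 7.80 in Smart-seq / C1, 9.34 ± 1.84 in Smart-seq2, 3.10 ± 0.522 in CEL-seq2, 6.52 ± 1.35 in MARS-seq, 7.95 ± 0.0961 in SCRB-seq and 0.0222 ± 0.0143 in Drop-seq percent of all counts. Drop-seq held 0.0121% in A and 0.0324% in B, too little to tell whether spike-ins were added there, and it stayed in the test. This spike-in share of counts did not pass the test (exact permutation p = 0.157, adjusted 0.157, with 67.00% of the sum of squares between methods). Smart-seq / C1 A held 14.3% and B 3.31%, and the spike-in p was 0.00135 without A and 9.62e-05 without B.

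**Figure D2:**
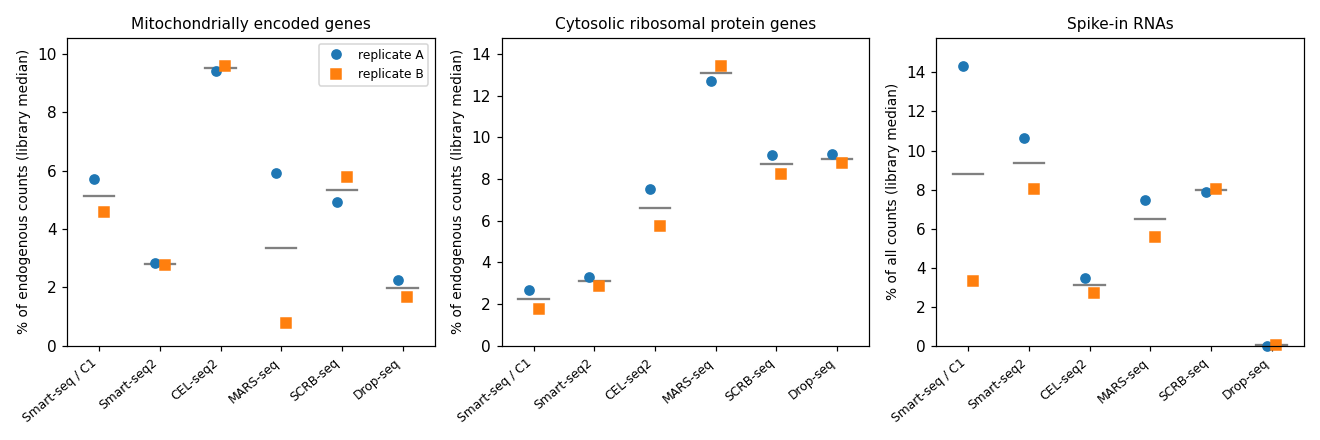
Share of counts (y axis, percent) taken by mitochondrially encoded genes, cytosolic ribosomal protein genes and ERCC spike-ins in each library, by method (x axis); points are library medians over cells, coloured by replicate, and grey lines their mean. Ribosomal protein genes hold 2.22 ± 0.616% in Smart-seq / C1 and 13.1 ± 0.521% in MARS-seq (mean ± SD, n = 2).

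The next comparison asks whether each method shows the cells as naive stem cells. Of the naive and core pluripotency list, the regulators that hold embryonic stem cells in self-renewal, the mean cell at 10000 counts showed 60.7 ± 4.36 in Smart-seq / C1, 67.8 ± 1.16 in Smart-seq2, 67.1 ± 4.76 in CEL-seq2, 55.2 ± 2.06 in MARS-seq, 60.4 ± 1.18 in SCRB-seq and 55.01 ± 2.36 in Drop-seq percent of the genes (± SD, n = 2). The methods differed in these pluripotency genes detected at 10000 counts (exact permutation p = 0.0243, adjusted 0.0325, with 84.96% of the sum of squares between methods). The unadjusted exact permutation p was above the threshold without 1 of 4 libraries: 0.0614 without Smart-seq2 A, 0.0576 without Smart-seq2 B, 0.0547 without MARS-seq A and 0.0548 without Drop-seq A. It was 0.0734 with the median over cells and 0.0956 with cells thinned to 5000 counts, so this difference depends on the summary and the depth. Nanog was counted in 80 of 80 thinned cells of Smart-seq2 A and 39 of 42 of Drop-seq A. Pou5f1, the gene of the core factor Oct4, was counted in 79 of 80 and 75 of 77 cells of Smart-seq2 A and B but in 28 of 69 and 12 of 61 of Smart-seq / C1 (unthinned 61 and 59).

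**Figure D3:**
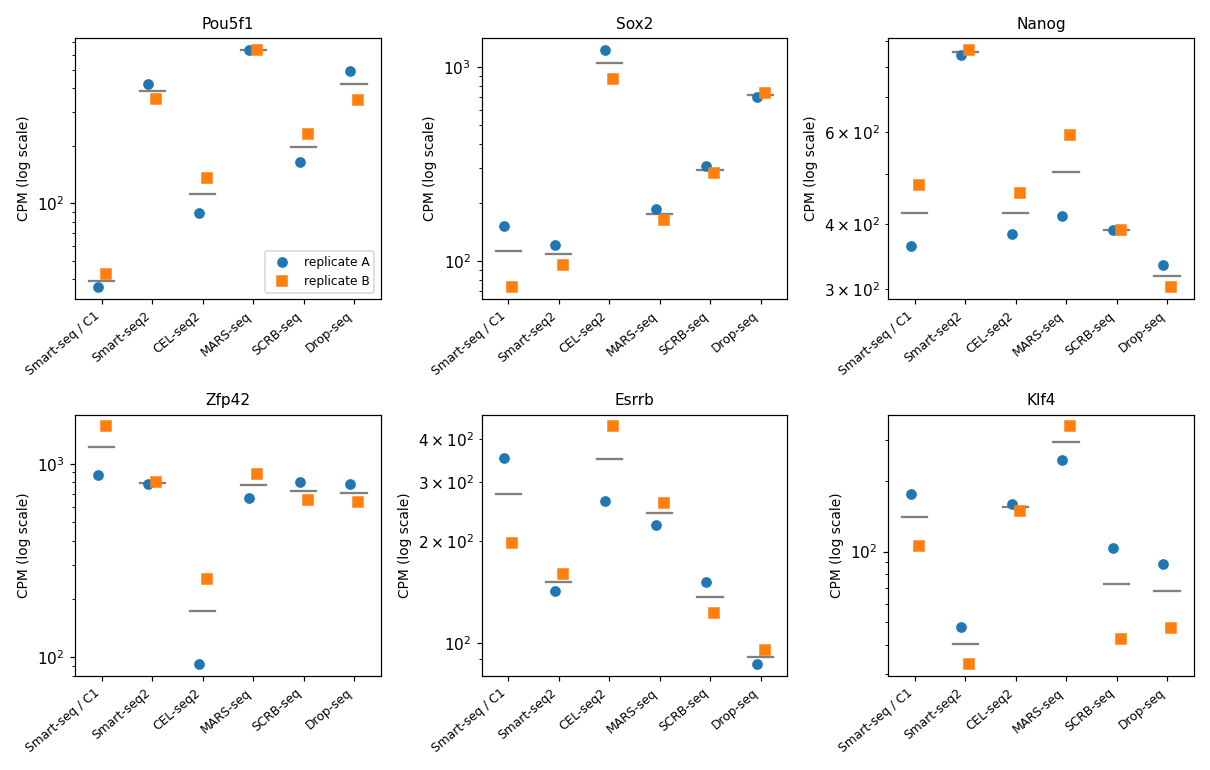
Expression (y axis, CPM on a log scale) of Pou5f1, Sox2, Nanog, Zfp42, Esrrb and Klf4 in the 12 libraries, by method (x axis); points are libraries, coloured by replicate, and grey lines their mean. Pou5f1 lies lowest in Smart-seq / C1 and CEL-seq2.

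Counts of genes with near-identical copies are uncertain, since the counting could split their reads. Of the genes named here and in the closing part, the following shared at least 10% of the 31-mers of their longest transcript with another gene: Arg2, AY074887, Calcoco2, Cdkn1a, Cox5a, Cox7c, Dppa5a, Eif5al3-ps, Fen1, Gm10132, Gm10800, Gm11464, Gm11869, Gm12165, Gm12245, Gm12481, Gm12696, Gm15310, Gm16585, Gm23493, Gm2574, Gm26384, Gm4540, Gm8172, Gm8357, Hist1h2af, Hist1h2ao, Hist1h4d, Hmgb2, Hmgcs1, Hsp25-ps1, Hsp90aa1, Hspa8, Hspe1, Lbr, Lefty2, Lsm7, Ly6a, Map3k12, Mif, mt-Nd3, mt-Nd4, mt-Nd4l, mt-Nd5, Mt2, Nanog, Nme2, Pou5f1, Psmb5, Rpl31, Rpl4, Rps12l1, Rps19-ps6, Rps29, Snhg3, Sumo2, Tfdp1, Ubb, Xist, Zfp42, Zfp868 and Zscan4b.

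Full-length methods were then set against 3' tag methods (n = 4 and 8 libraries), which asks which transcripts depend on where along the RNA they are read. Sox2, a core regulator of the stem cell state (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461 on GRCm38), fell in the full-length methods to 111 ± 33.5 CPM (SD, n = 4) against 557 ± 381 CPM (n = 8), log2 fold change -2.001, adjusted p = 1.06e-06. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) fell from 342 ± 224 to 213 ± 203 CPM (log2 fold change -1.17, adjusted p = 0.00014), and Klf4 by a log2 fold change of -0.71. For Pou5f1 only Smart-seq / C1 was lower, while Smart-seq2 lay above the mean of the tag libraries. Nanog (0.57) and Zfp42 (0.94), a marker of the naive state, rose, and Esrrb did not pass (0.18, adjusted p = 0.517). Over the whole naive and core list 15 of 37 rose and 6 fell (15 and 6 adjusted over the list alone), with Sall4 (1.91) leading, and the list was not called.

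Lists of short transcripts were lower in the full-length methods. For the replication-dependent histone genes, whose small RNAs encode the proteins that package new DNA in S phase, the median log2 fold change was -2.76 (camera adjusted p = 1.14e-09, adjusted p = 0.282 with an estimated correlation). Of 42 genes 0 rose and 34 fell (0 and 36 adjusted over the list alone). Hist1h2ao (ENSMUSG00000094248, chromosome 13, 21810465 to 21810944) had 7 reads in all full-length libraries and 2404 ± 2796 CPM in the tag libraries. Cytosolic ribosomal protein genes had a median of -2.10 (camera adjusted p = 2e-17, adjusted p = 0.538 with an estimated correlation). Of 86 genes 2 rose and 73 fell (2 and 74 adjusted over the list alone). Rps29 (-6.23), Rpl31 (-4.78) and Rpl4 (-0.65), the most highly expressed of them, were among those that fell. The mitochondrial genes mt-Nd3 and mt-Nd4l, subunits of complex I, had no read in any full-length library and were at least 29342-fold and 18842-fold lower there (floor of 3 counts over the group), against 769 and 494 CPM in the tag libraries. The pseudogene Gm12481 was likewise at 0, at least 31819.8-fold lower. ENSMUSG00000083840 and Gm26384 had 2 reads each against 777 and 757 CPM.

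Other lists moved the other way. Among all tested genes, those of over 2000 to 4000 nt had a median of 0.59 and those of over 4000 to 8000 nt 0.50. The lists below were not tested with the trend on transcript length removed. G1/S genes, which prepare and run DNA replication, had a median of 0.92 (camera adjusted p = 3.9e-05, adjusted p = 0.538 with an estimated correlation). Of 44 genes 32 rose and 3 fell (33 and 3 adjusted over the list alone). Mcm4, part of the replicative helicase, rose (1.55) and Fen1, a flap endonuclease, fell (-3.17). G2/M genes, which run mitosis, had a median of 0.71 (camera adjusted p = 0.000595, adjusted p = 0.712 with an estimated correlation). Of 52 genes 30 rose and 1 fell (31 and 1 adjusted over the list alone), with Lbr up (1.76) and Hmgb2 down (-2.86). The unfolded protein response, the chaperones and sensors of the endoplasmic reticulum, had a median of 0.54 (camera adjusted p = 0.0175, adjusted p = 0.538 with an estimated correlation). Of 18 genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), led by Canx (1.89) and Pdia3 (1.82). Targets of p53 had a median of 0.86 (camera adjusted p = 0.0305, adjusted p = 0.538 with an estimated correlation). Of 21 genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Trp53 (2.003) and Aen (2.14). Cholesterol synthesis genes had a median of 0.58 (camera adjusted p = 0.0314, adjusted p = 0.637 with an estimated correlation). Of 24 genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Hmgcs1 (1.56). The single genes with the largest rises were Gsdme (ENSMUSG00000029821, chromosome 6, 50188888 to 50263862), at 241 ± 223 CPM (SD, n = 4) against 2.33 ± 2.15 CPM (n = 8), then Eif5al3-ps (5.28), Zfp868 (4.03), Tfdp1 (3.99) and Dcp1a (3.56).

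The other 19 lists, the naive and core list among them, were not called (camera adjusted p from 0.0578 to 0.932). Below, up and down count their genes that passed, with counts adjusted over the list alone in brackets. Proteasome genes had 15 up and 4 down of 31 (16 and 4), with Psmc6 (1.38) and Psmb5 (-1.77). Nuclear genes of oxidative phosphorylation had 15 up and 30 down of 74 (17 and 31), with Atp5b (1.16) and Cox7c (-3.15). Mitochondrial ribosomal protein genes had 22 up and 14 down of 76 (22 and 14), with a median of 0.16 and a mean of -0.01. All mitochondrially encoded genes had 5 up and 8 down of 25 (5 and 9). Their protein genes alone had 3 up and 3 down of 9 (3 and 3), with a median of 0.35, a mean of -2.78 and camera downward. Immediate early and heat shock genes had 8 up and 7 down of 27 (8 and 8), with Hspe1 (-2.50) and Hsp90aa1 (-1.96). The integrated stress response had 9 up and 3 down of 23 (10 and 3), with Slc7a3 (1.81). Glycolysis and hypoxia genes had 10 up and 4 down of 28 (11 and 4), with Mif (-2.50) and Hk2 (1.43). Imprinted genes had 5 up and 5 down of 20 (5 and 5), with Gnas (-5.83), Impact (2.68), a median of 0.38 and a mean of -0.25. Nuclear and non-polyadenylated RNAs had 4 up and 8 down of 19 (4 and 8), with Snhg3 (-7.81) and Malat1 (0.71). The giant coding genes had 15 up and 4 down of 44 (14 and 4), with Kmt2d (2.45). Among markers of other states, primed pluripotency had 3 up and 3 down of 10 (3 and 3), with a median of 0.74 and a mean of -0.11. For 2-cell-like genes there were 1 up and 0 down of 12 (1 and 0), for mesendoderm 3 up and 0 down of 6 (3 and 0), for neural genes 1 up and 0 down of 6 (1 and 0) and for fibroblast genes 0 up and 4 down of 10 (0 and 3). Primitive endoderm had 0 up and 0 down of 6 (0 and 0). Trophectoderm had 0 up and 0 down of 10 (0 and 0), with a median of -0.17, a mean of -0.10 and camera upward.

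In edgeR's quasi-likelihood test of full-length against 3' tag methods 6975 of 14293 genes passed (3653 higher and 3322 lower), and 7787 had an unadjusted p under 0.05. Higher calls were 52.4%, but 69.9% of 8916 by limma on the mean over cells of log2 CPM plus 1. For 2498 genes (17.5%) every full-length library lay on one side of every tag library, against 0.404% by chance if all libraries were exchangeable. Replicates of a method are alike, so the share by chance would be higher with methods kept whole. The direction followed transcript length (Spearman 0.44 across 14156 genes, which are not independent). Genes with transcripts of up to 500 nt had a median of -5.71 (19 rose and 915 fell of 1211), and those of over 500 to 1000 nt -3.33. It was 0.05 for over 1000 to 2000 nt and, for over 2000 to 4000 nt, 0.59 (1717 rose and 572 fell of 4885). DESeq2 size factors moved the median log2 fold change of all tested genes from 0.21 to 0.07 here. They moved it from 0.19 to 0.02 for CEL-seq2 against MARS-seq, from -0.09 to 0.11 for Drop-seq against SCRB-seq and from -0.07 to 0.13 for the C1 difference, so small changes are relative to these medians. Klf4 did not pass without CEL-seq2 A (0.0573), Drop-seq A (0.108), Drop-seq B (0.0862), MARS-seq B (0.0792), SCRB-seq A (0.108), Smart-seq / C1 B (0.114), Smart-seq2 A (0.123) or Smart-seq2 B (0.369), with the adjusted p in brackets. Rpl4 did not pass without Drop-seq B (0.151), Smart-seq / C1 A (0.167), Smart-seq2 A (0.234) or Smart-seq2 B (0.202).

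**Figure D4:**
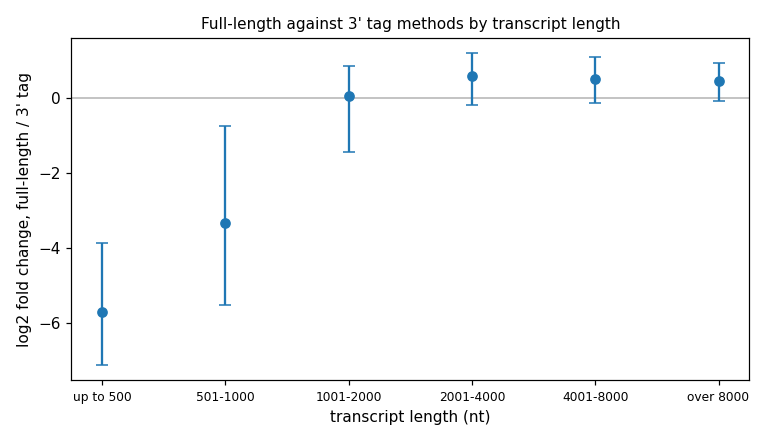
Log2 fold change of full-length against 3' tag methods (y axis) in bins of transcript length (x axis, nt); points are medians over genes and bars the quartiles. The median runs from -5.71 at up to 500 nt to 0.46 above 8000 nt.

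Smart-seq / C1 against Smart-seq2 compares both full-length methods (n = 2 libraries each). Slc34a2, a sodium-phosphate cotransporter (ENSMUSG00000029188, chromosome 5, 53038081 to 53071664), stood at 9.31 ± 11.5 CPM (SD, n = 2) against 15962 ± 5252 CPM (n = 2), log2 fold change -10.73, adjusted p = 0.00175. Pou5f1 fell in Smart-seq / C1 to 39.3 ± 4.28 against 387 ± 50.3 CPM (log2 fold change -3.30, adjusted p = 3.71e-05), as did Nanog (-1.03) and Utf1 (-3.04), while Klf4 rose (1.80). The naive and core list as a whole had a median of 0.17 (quartiles -0.52 to 1.21) and was not called. Egr1, an immediate early transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), rose to 276 ± 272 against 1.52 ± 0.666 CPM (log2 fold change 7.50, adjusted p = 0.000105). Egr1 was counted in 61 of 69 thinned cells of Smart-seq / C1 A and 19 of 61 of B, and in 0 of 80 and 0 of 77 of Smart-seq2 A and B. Without thinning it was counted in 8 and 9 cells of Smart-seq2 A and B. Other large rises were B830012L14Rik (5.76), Enc1 (5.74), Gm8172 (4.36) and Gm16585 (4.09), and other large falls Gm26917 (-7.66), Slc16a3, a lactate carrier (-5.71), and n-R5-8s1 (-5.60). The pseudogene Hsp25-ps1 had 1 read in Smart-seq / C1, 0.0237 against 2.35 CPM.

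The giant coding genes, with transcripts of over 8 kb, were higher as a group in Smart-seq / C1, with a median of 1.37 (camera adjusted p = 3.04e-12, adjusted p = 0.276 with an estimated correlation). Of 44 genes 23 rose and 0 fell (33 and 0 adjusted over the list alone). Among them were Ranbp2 (2.48) and Tpr (1.55), both of the nuclear pore, and Nf1 (2.99). Long transcripts in general were higher here. Of all 675 tested genes with transcripts of over 8000 nt, 216 rose and 5 fell, with quartiles of 0.28 to 1.76. Genes of over 4000 to 8000 nt had a median of 0.44. The list result was not tested apart from transcript length, so it may only restate that trend. Nuclear oxidative phosphorylation genes went the other way, with a median of -0.56 (camera adjusted p = 1.53e-05, adjusted p = 0.538 with an estimated correlation). Of 74 genes 1 rose and 16 fell (1 and 17 adjusted over the list alone), with Cox8a (-2.37) and Cox5a (-1.65). Cytosolic ribosomal protein genes had a median of -0.26 (camera adjusted p = 0.0213, adjusted p = 0.802 with an estimated correlation). Of 86 genes 3 rose and 12 fell (3 and 13 adjusted over the list alone). Mitochondrial ribosomal protein genes had a median of -0.26 (camera adjusted p = 0.0213, adjusted p = 0.712 with an estimated correlation). Of 76 genes 1 rose and 9 fell (0 and 8 adjusted over the list alone). The glycolysis and hypoxia list had a median of -0.60 (camera adjusted p = 0.0141, adjusted p = 0.773 with an estimated correlation). Of 28 genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with Slc2a1, the main glucose carrier, down (-2.65) and Hk2 up (2.23). The integrated stress response had a median of -0.55 (camera adjusted p = 0.032, adjusted p = 0.538 with an estimated correlation). Of 23 genes 0 rose and 3 fell (0 and 3 adjusted over the list alone). The 2-cell-like list, genes of rare cells resembling the early embryo, had a median of 5.87, or 5.42 with genes at 0 on one side set to the floor (camera adjusted p = 0.0345, adjusted p = 0.786 with an estimated correlation). Of 12 genes 3 rose and 0 fell (3 and 0 adjusted over the list alone). Zscan4 genes of this list were counted in 1 of 69 thinned cells of Smart-seq / C1 A and 8 of 61 of B, where 2 cells held 86.2% of 3381 reads. Of the genes that rose, Arg2 and Eif1a did not pass without Smart-seq / C1 B (adjusted p = 0.321 and 0.229), without Smart-seq2 A (0.0954 and 0.181) or without Smart-seq2 B (0.116 and 0.147).

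By edgeR's test of Smart-seq / C1 against Smart-seq2, 2223 of 14293 genes passed (1250 higher and 973 lower), and 4282 had an unadjusted p under 0.05. Higher calls were 56.2% here and 12.2% of 2082 by limma on the mean over cells, which does not match depth between cells. Libraries did not overlap for 9002 genes (62.98%, against 33.3% by chance). The count was 614 without Smart-seq2 A and 622 without Smart-seq2 B. Some genes named here did not pass without 1 library (adjusted p in brackets). Without Smart-seq / C1 B this held for Gm8172 (0.107). Without Smart-seq2 A these were Gm8172 (0.144), Klf4 (0.0522) and Nanog (0.16). Without Smart-seq2 B these were Gm8172 (0.0851), Klf4 (0.142), Nanog (0.172) and Tpr (0.104). Without Smart-seq / C1 A this held for Nanog (0.0513).

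In vitro transcription methods were compared with the PCR tag methods (n = 4 libraries each). The naive and core list was higher as a group, with a median of 0.30 (camera adjusted p = 0.0267, adjusted p = 0.538 with an estimated correlation). Of 37 genes 14 rose and 3 fell (14 and 3 adjusted over the list alone). Klf4 stood at 225 ± 89.97 CPM (SD, n = 4) against 70.3 ± 30.3 CPM (n = 4) (log2 fold change 1.60, adjusted p = 0.00166), Esrrb rose (1.38, adjusted p = 0.000985) and so did Utf1 (1.81). Zfp42 (-0.96) and Dppa5a (-2.56) fell, and Pou5f1 (-0.11), Sox2 (-0.11) and Nanog (0.39) did not pass. Integrated stress response genes, which rise when amino acids run short, had a median of 0.61 (camera adjusted p = 0.0294, adjusted p = 0.538 with an estimated correlation). Of 23 genes 7 rose and 2 fell (9 and 2 adjusted over the list alone), with Shmt2 (1.79) up and Sars (-1.91) down. Giant coding genes were lower as a group, with a median of -0.61 (camera adjusted p = 0.0101, adjusted p = 0.538 with an estimated correlation). Of 44 genes 0 rose and 15 fell (1 and 18 adjusted over the list alone), led by Cenpe (-1.95) and Ankrd11 (-1.98). No 2-cell-like gene passed by itself (0 over the list alone too), but the list had a median of -8.09, or -5.05 at the floor (camera adjusted p = 0.0267, adjusted p = 0.773 with an estimated correlation). Zscan4b had no count in the in vitro transcription libraries against 10.3 ± 15.6 CPM (adjusted p = 0.0532). In SCRB-seq A 2 cells held 49.7% of 630 UMIs of Zscan4 genes.

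The largest single rises were Gm2574 (4.65), the annotated miRNA gene Gm23493 (4.58), Hist1h2af (4.41), Cmtm7 (4.08) and Ly75 (3.78). The largest falls were in lincRNA genes, pseudogenes and a predicted coding gene: Gm11464 (-10.15), Gm15310 (-8.34), Gm17087 (-7.42), Gm26710 (-7.18) and Gm10132 (-6.76). By edgeR's test of in vitro transcription against PCR tag methods, 3144 of 14293 genes passed (1307 higher and 1837 lower), and 5035 had an unadjusted p under 0.05. Libraries did not overlap for 1966 genes (13.8%, against 2.86% by chance if all tag libraries were exchangeable). Here too the share by chance would be higher with methods kept whole. Without Drop-seq A the count was 1910. Zfp42 did not pass without CEL-seq2 A (0.0729), Drop-seq A (0.0887), Drop-seq B (0.0571), MARS-seq A (0.0922) or SCRB-seq A (0.0797), with the adjusted p in brackets.

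CEL-seq2 against MARS-seq compares both in vitro transcription methods, the first on the C1 chip (n = 2 libraries each). The core factors moved apart in CEL-seq2. Pou5f1 fell to 112 ± 33.1 CPM (SD, n = 2) against 639 ± 0.0654 CPM (n = 2) (log2 fold change -2.51, adjusted p = 4.5e-05). Zfp42 fell to 172 ± 113 against 776 ± 158 CPM (log2 fold change -2.16, adjusted p = 0.00117). Sox2 rose to 1043 ± 257 against 174 ± 16.8 CPM (log2 fold change 2.58, adjusted p = 6.65e-05). Nanog (-0.26), Esrrb (0.53) and Klf4 (-0.93) did not pass. Jarid2, a partner of the Polycomb complex, rose (3.49), and Dppa5a, a marker of naive cells, fell (-4.41). The naive and core list as a whole had a median of 0.53 (quartiles -0.23 to 1.45) and was not called.

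Direction followed transcript length in this contrast as well, with a median of -2.55 for genes of up to 500 nt (52 rose and 541 fell of 1211). The median was -1.59 for over 500 to 1000 nt and 0.68 for over 4000 to 8000 nt. Ribosomal protein genes were lower as a group in CEL-seq2, with a median of -2.48 (camera adjusted p = 4.43e-19, adjusted p = 0.538 with an estimated correlation). Of 86 genes 5 rose and 62 fell (6 and 68 adjusted over the list alone). Among those that rose was Rpl4 (2.10). Histone genes had a median of -3.54 (camera adjusted p = 4.24e-15, adjusted p = 0.276 with an estimated correlation). Of 42 genes 0 rose and 27 fell (0 and 28 adjusted over the list alone), and Hist1h1b had no UMI in CEL-seq2, at least 537-fold lower. Nuclear oxidative phosphorylation genes were lower too, with a median of -1.002 (camera adjusted p = 1.31e-08, adjusted p = 0.538 with an estimated correlation). Of 74 genes 3 rose and 39 fell (3 and 43 adjusted over the list alone), with Cox7c at 44.8 ± 16.6 against 1829 ± 334 CPM. Mitochondrial ribosomal protein genes had a median of -0.75 (camera adjusted p = 0.000333, adjusted p = 0.538 with an estimated correlation). Of 76 genes 4 rose and 30 fell (5 and 33 adjusted over the list alone). Genes encoded in the mitochondrion itself went the other way as a group. Protein genes among them had a median of 2.71 (camera adjusted p = 0.0162, adjusted p = 0.744 with an estimated correlation). Of 9 genes 6 rose and 0 fell (6 and 0 adjusted over the list alone). All together had a median of 2.03, or 0.63 at the floor (camera adjusted p = 0.0213, adjusted p = 0.802 with an estimated correlation). Of 25 genes 6 rose and 0 fell (6 and 0 adjusted over the list alone). Examples were mt-Nd3 (8.88) and mt-Nd4 (3.48), beside the mitochondrial shares of 5.91% and 0.782% in MARS-seq A and B. The primed pluripotency list had a median of 2.44 (camera adjusted p = 0.0342, adjusted p = 0.538 with an estimated correlation). Of 10 genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), among them Otx2 (41.8 against 2.38 CPM) and Zic2 (18.3 against 2.38 CPM), each with 3 UMIs in MARS-seq.

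Other large rises in CEL-seq2 were Syt11 (6.42), Ly6a (5.93) and Zc3hav1l (5.62), and AY074887, with no UMI in MARS-seq, was at least 23.96-fold higher. Nme2, a nucleoside diphosphate kinase, and Gm12245 had no UMI in CEL-seq2, at least 287-fold and 194-fold lower. Rps12l1 and Gm12165 had 1 UMI each there, against 290.0 and 276 CPM in MARS-seq. By edgeR's test of CEL-seq2 against MARS-seq, 3341 of 14293 genes passed (1569 higher and 1772 lower), and 5070 had an unadjusted p under 0.05. Of these calls 46.96% were higher, against 81.1% of 6427 by limma on the mean over cells, which does not match depth between cells. Libraries did not overlap for 8903 genes (62.3%, against 33.3% by chance). The count was 2014 without CEL-seq2 B, 1979 without MARS-seq A and 1936 without MARS-seq B. Some genes named here did not pass without 1 library (adjusted p in brackets). Without MARS-seq B these were AY074887 (0.0504), Ly6a (0.137), Otx2 (0.134) and Zic2 (0.205). Without CEL-seq2 A these were Hist1h1b (0.0582), Ly6a (0.0641), Otx2 (0.27) and Zic2 (0.0633). Without CEL-seq2 B these were Hist1h1b (0.0825) and Zic2 (0.0864). Without MARS-seq A these were Hist1h1b (0.0505), Ly6a (0.175), Otx2 (0.0536) and Zic2 (0.0621). Without Smart-seq2 A these were Hist1h1b (0.0561), Ly6a (0.106) and Zic2 (0.0521). Without Smart-seq2 B these were Hist1h1b (0.0567), Ly6a (0.106) and Zic2 (0.0507). Without Drop-seq B this held for Zic2 (0.0527).

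Drop-seq against SCRB-seq compares the PCR tag methods (n = 2 libraries each), droplets against sorted cells. No core factor passed, with Sox2 at 716 ± 20.8 CPM (SD, n = 2) against 296 ± 15.8 CPM (n = 2) (log2 fold change 1.27, adjusted p = 0.0722). Pou5f1 stood at 420.1 ± 104 against 198 ± 47.7 CPM (log2 fold change 1.08, adjusted p = 0.0971). Lars2, a mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), fell in Drop-seq to 39.8 ± 5.98 against 1292 ± 488 CPM (log2 fold change -5.01, adjusted p = 0.000824), with Mir6236 (-6.70), Hist1h4d (-5.62), Gm8357 (-4.57) and Gm15564 (-4.51). Vps8, which tethers endosomal membranes, rose to 878 ± 754 against 12.98 ± 1.37 CPM (log2 fold change 6.08, adjusted p = 0.000338), with Gm11869 (5.55), Gm13423 (4.61) and Map3k12 (4.34). Gm10800 had 1 UMI in SCRB-seq, 53.4 against 0.222 CPM.

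Camera called 5 lists. Nuclear oxidative phosphorylation genes had a median of -0.43 (camera adjusted p = 0.000428, adjusted p = 0.538 with an estimated correlation). Of 74 genes 0 rose and 1 fell (0 and 7 adjusted over the list alone), with Cox8a (-1.55) the gene that fell. Histone genes had a median of -0.82 (camera adjusted p = 0.00184, adjusted p = 0.538 with an estimated correlation). Of 42 genes 0 rose and 5 fell (0 and 9 adjusted over the list alone). For the giant coding genes the median was -0.57 (camera adjusted p = 0.0175, adjusted p = 0.538 with an estimated correlation). Of 44 genes 0 rose and 2 fell (1 and 8 adjusted over the list alone), among them Ubr4 (-1.43) and Herc2 (-2.04). Mitochondrial ribosomal protein genes had a median of -0.49 (camera adjusted p = 0.00337, adjusted p = 0.637 with an estimated correlation). Of 76 genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), which was Mrpl13 (-1.38). Neural genes had a median of 1.45 (camera adjusted p = 0.0363, adjusted p = 0.538 with an estimated correlation). Of 6 genes 0 rose and 0 fell (2 and 0 adjusted over the list alone).

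By edgeR's test of Drop-seq against SCRB-seq, 216 of 14293 genes passed (147 higher and 69 lower), and 2591 had an unadjusted p under 0.05. Libraries did not overlap for 7282 genes (50.9%, against 33.3% by chance). The share of higher calls was 68.1%, and 86.2% of 325 with DESeq2 size factors. By limma on the mean over cells it was 11.5% of 3977, the opposite balance. The count fell without any one of the compared libraries, which leaves its method without a replicate. It also fell without either Smart-seq2 library and rose without either Smart-seq / C1 library. Those libraries enter this contrast only through the scaling and the shared estimate of the spread. Some genes named here did not pass without 1 library (adjusted p in brackets). Without Drop-seq A these were Cox8a (0.139), Gm10800 (0.0562), Gm8357 (0.211), Herc2 (0.297), Hist1h4d (0.0746), Mrpl13 (0.205) and Ubr4 (0.282). Without Drop-seq B these were Cox8a (0.289), Gm8357 (0.153), Herc2 (0.158), Mrpl13 (0.265) and Ubr4 (0.142). Without MARS-seq A these were Cox8a (0.0531), Herc2 (0.0534), Mrpl13 (0.0545) and Ubr4 (0.0545). Without MARS-seq B these were Cox8a (0.0543), Herc2 (0.0541), Mrpl13 (0.055) and Ubr4 (0.0547). Without SCRB-seq A these were Cox8a (0.177), Gm10800 (0.0741), Gm11869 (0.0603), Gm8357 (0.147), Herc2 (0.276), Mrpl13 (0.185) and Ubr4 (0.16). Without SCRB-seq B these were Cox8a (0.183), Gm10800 (0.0969), Gm13423 (0.0585), Gm8357 (0.146), Herc2 (0.105), Map3k12 (0.0822), Mrpl13 (0.191) and Ubr4 (0.189). Without Smart-seq2 A these were Cox8a (0.0622), Gm8357 (0.0526), Herc2 (0.0774), Mrpl13 (0.0962) and Ubr4 (0.08). Without Smart-seq2 B these were Cox8a (0.0622), Gm8357 (0.0521), Herc2 (0.0787), Mrpl13 (0.0964) and Ubr4 (0.0799).

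Lastly, the change from partner method to C1 method was compared between chemistries (n = 2 libraries in each of 4 methods), that is, Smart-seq / C1 against Smart-seq2 less CEL-seq2 against MARS-seq. Chip and method change together in each pair, so the chip cannot be told apart from the rest of the method. A positive difference means that this change was more positive on the Smart-seq side, not that expression was higher there. Higher and lower refer to the difference in what follows. Pou5f1 fell on both sides (-3.30 and -2.51), and its difference did not pass (-0.79, adjusted p = 0.264). Sox2 (-2.53), Zfp42 (2.78) and Klf4 (2.73) differed. Genes with transcripts of up to 500 nt had a median difference of 2.55 (292 higher and 37 lower of 1211). Ribosomal protein genes differed as a group, with a median of 1.97 (camera adjusted p = 3.59e-13, adjusted p = 0.538 with an estimated correlation). Of 86 genes 49 were higher and 5 lower (53 and 6 adjusted over the list alone). Histone genes did so too, with a median of 3.20 (camera adjusted p = 3.71e-10, adjusted p = 0.282 with an estimated correlation). Of 42 genes 13 were higher and 0 lower (15 and 0 adjusted over the list alone), as with Hist1h1a (8.71). For nuclear oxidative phosphorylation genes the median was 0.54 (camera adjusted p = 0.0314, adjusted p = 0.712 with an estimated correlation). Of 74 genes 17 were higher and 5 lower (22 and 8 adjusted over the list alone), with Cox7c (5.38). The giant coding genes had a median of 0.88 (camera adjusted p = 0.0153, adjusted p = 0.538 with an estimated correlation). Of 44 genes 10 were higher and 1 lower (12 and 2 adjusted over the list alone), with Mki67 (2.91).

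For p53 targets the median was -0.74 (camera adjusted p = 0.0489, adjusted p = 0.538 with an estimated correlation). With a replicate block this list was no longer called (adjusted p = 0.0563). Of 21 genes 0 were higher and 5 lower (0 and 5 adjusted over the list alone), with Phlda3 (-3.97) and Cdkn1a (-3.09). For primed pluripotency the median was -2.87 (camera adjusted p = 0.0213, adjusted p = 0.538 with an estimated correlation). Of 10 genes 0 were higher and 1 lower (0 and 4 adjusted over the list alone), with Zic2 (-3.79). Among single genes the chaperone gene Hspa8 (6.65) and the ubiquitin gene Ubb (5.91) were higher. By edgeR's test of the C1 difference between chemistries 2246 of 14293 genes passed (1227 higher and 1019 lower), and 4227 had an unadjusted p under 0.05. Of these 54.6% were higher, but 13.1% of 6485 by limma on the mean over cells. The count was 1121 without Smart-seq2 A, 1205 without Smart-seq2 B and 1446 without MARS-seq A. Zic2 did not pass without CEL-seq2 A (0.0684), CEL-seq2 B (0.0877), Drop-seq B (0.0698), MARS-seq A (0.0601), MARS-seq B (0.164), Smart-seq / C1 A (0.0688), Smart-seq2 A (0.157) or Smart-seq2 B (0.0759), with the adjusted p in brackets.

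The last comparison asks which genes vary from cell to cell beyond the Poisson spread of counts. Over 506 genes with enough counts in every library at 10000 counts per cell, the median log2 of the extra-Poisson variance was -2.39 ± 0.08 in Smart-seq / C1, -3.41 ± 0.09 in Smart-seq2, -3.99 ± 0.56 in CEL-seq2, -2.31 ± 0.39 in MARS-seq, -4.89 ± 0.46 in SCRB-seq and -2.59 ± 0.37 in Drop-seq (± SD, n = 2). It differed between methods (exact permutation p = 0.00164, adjusted 0.00436, with 92.8% of the sum of squares between methods). Smart-seq reads carry no UMI, so their values also hold copies made in amplification and are not cell-to-cell variation on the same scale as UMI counts. Against the trend of variation on mean, 74 of 2656 genes were more variable and 71 less variable across the 12 libraries (limma with Benjamini-Hochberg adjustment, 504 at an unadjusted p under 0.05). The most variable were the mitochondrial rRNA mt-Rnr1 (1.59 ± 0.16), the nuclear RNA Malat1 (1.55 ± 0.09) and the metallothioneins Mt1 (1.54 ± 0.11) and Mt2 (1.35 ± 0.10), which bind zinc and copper (mean residual log2 squared coefficient of variation ± SE, n = 12). The SE is limma's moderated one from the spread between replicates of a method and leaves out the spread between methods. Single libraries ran from -0.31 to 4.66 for mt-Rnr1 and from 0.40 to 3.17 for Malat1. These genes were followed by mt-Rnr2 (1.24 ± 0.25), Trh (1.12 ± 0.13), Lefty2 (1.11 ± 0.10), an antagonist of Nodal, Sdc4 (0.99 ± 0.11), Apoe (0.96 ± 0.12), Sgk1 (0.86 ± 0.11), mt-Nd4 (0.83 ± 0.15), mt-Cytb (0.83 ± 0.13), Top2a (0.80 ± 0.10), a mitotic topoisomerase, Calcoco2 (0.78 ± 0.09) and mt-Nd5 (0.70 ± 0.14).

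By list, 8 of 9 (9 adjusted over the list alone) mitochondrially encoded genes were more variable, as were 7 of 43 (9 adjusted over the list alone) G2/M genes, 3 of 7 (4 adjusted over the list alone) p53 targets and 4 of 16 (4 adjusted over the list alone) glycolysis and hypoxia genes. Of the glycolysis and hypoxia genes 1 was less variable (2 adjusted over the list alone). Of the naive and core list, 4 of 26 (4 adjusted over the list alone) were more variable, and of the core factors Klf4 passed (0.37 ± 0.11, adjusted p = 0.037). Zfp42 (0.22), Sox2 (0.14), Nanog (0.06), Pou5f1 (-0.11) and Esrrb (-0.15) did not. Ribosomal protein genes were less variable in 22 of 57 (33 adjusted over the list alone) and nuclear oxidative phosphorylation genes in 7 of 64 (8 adjusted over the list alone). Residuals of single genes correlated weakly between libraries, on average 0.183 within a method and 0.0799 between methods (Spearman, across genes, which are not independent). The number of genes variable among cells across methods was 44 without Smart-seq / C1 B, 32 and 38 without Smart-seq2 A or B, 46 without CEL-seq2 A, and 47 and 42 without SCRB-seq A or B.

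**Figure D5:**
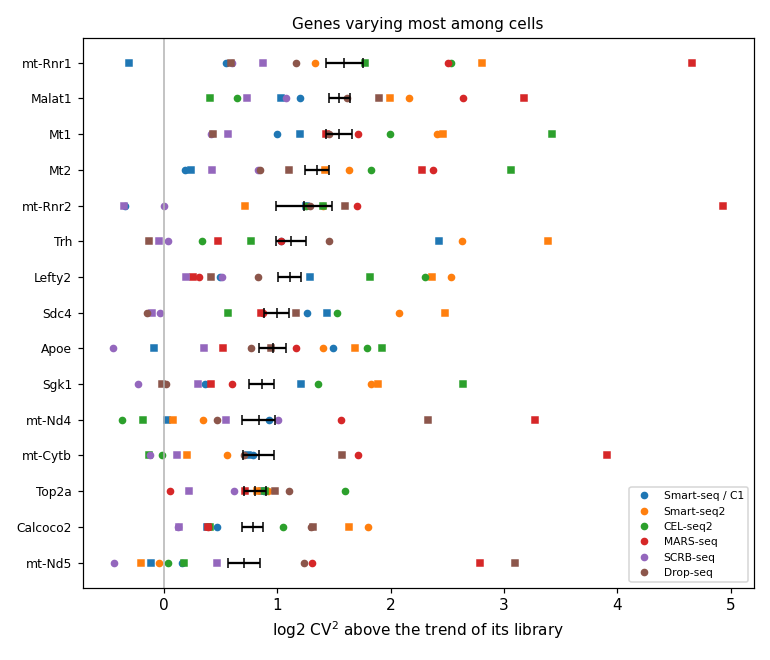
Mean residual of the log2 squared coefficient of variation (x axis) of the 15 most variable genes (y axis) over the 12 libraries; black bars are means with standard errors from the spread within methods and points single libraries, coloured by method. Malat1, Mt1, Mt2, Lefty2, Top2a and Calcoco2 lie above the trend in all 12 libraries.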

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

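The tests of Pou5f1 and of the Drop-seq barcodes were chosen only after the results were seen. The change from partner method to C1 method differed between chemistries for 2246 genes, by the edgeR test of the difference itself. Among genes that passed with an average log2 CPM of at least 5 and libraries that did not overlap, the largest positive differences on the log2 scale were Rps19-ps6 (8.61), Gm12696 (6.78), Sumo2 (6.50), Ubb (5.91) and Lsm7 (5.74). The largest negative differences among them were Dqx1 (-6.80), Zfp771 (-6.07), Gm4540 (-6.05), Ptk7 (-5.97) and Pip4k2c (-5.64). Of the core factors Sox2 (-2.53), Zfp42 (2.78) and Klf4 (2.73) differed. Among lists the camera adjusted p passed for primed pluripotency (0.0213), p53 targets (0.0489), nuclear oxidative phosphorylation (0.0314), histones (3.71e-10), giant coding genes (0.0153) and ribosomal protein genes (3.59e-13), and none of them passed with an estimated correlation. Groups held 2 libraries each, too few to look for single libraries far from their group.

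The splits of single libraries bear on chance only for that division, not for the grouping of methods. Most other splits mix libraries of methods that differ, so few calls were likely in them beforehand. Of 100 such splits, 1 gave as many genes between full-length and 3' tag methods, the real one with 6975, and the highest other gave 1550. For in vitro transcription against PCR tag methods 1 of 35 gave as many (3144 genes, highest other 1300). These splits part the replicates of a method, so they say nothing on how methods were grouped, and for in vitro transcription against PCR only 3 of them keep methods whole, too few for a share under 0.05. With the 6 methods kept whole in full-length against 3' tag methods, the 15 splits are too few for a share under 0.05. The real one called 6975 genes and the highest other, SCRB-seq with Drop-seq, 5323.

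Ribosomal protein and histone genes were lower in full-length methods. Reads shared with gene copies are argued against as the whole cause for ribosomal protein genes, since the 10 members with under 10% shared 31-mers kept a median log2 fold change of -1.10 (95% interval of the median -1.54 to -0.76). For histones this cannot be told apart, with too few such members (4), at a median of -1.95. Transcript length may account for most of both: removing its trend over all genes moved the ribosomal protein median from -2.10 to -0.37 (interval -1.37 to -0.11) and the histone median from -2.76 to -0.19 (-1.18 to 0.70), intervals that reach below the bound of -0.5 set beforehand. The lists are part of that trend, read and UMI counting differ between the same groups, and no biological explanation was tested.

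Pou5f1 was lower in both C1 methods than in their partners, but the chip cannot be told apart from the rest of each method. For Smart-seq / C1 reads shared with gene copies cannot be told apart as a cause, because the 3190 genes sharing at least as many 31-mers as Pou5f1 (22.7%) went both ways, with a median log2 fold change of 0.09 (quartiles -0.75 to 1.12). In CEL-seq2 against MARS-seq the same genes had a median of -1.09 (95% interval of the median -1.21 to -0.97, quartiles -3.50 to 0.42) and the 9444 genes under 10% had 0.46, so shared reads are a candidate explanation there. For other groups lower in CEL-seq2, members under 10% had medians of -1.01 for ribosomal protein genes (10 members, interval -2.44 to -0.60), which argues against it as the whole cause since the interval lies below -0.5, and of -0.78 for oxidative phosphorylation and -0.52 for mitochondrial ribosomal protein genes, where it cannot be told apart because both lie between the bounds set beforehand. Transcript length was not tested as a cause in CEL-seq2 against MARS-seq, where genes of up to 500 nt had a median of -2.55. Length and shared reads therefore cannot be told apart there. Lower naive pluripotency in the C1 libraries cannot be told apart, because the members of the naive and core list went both ways, with medians of 0.17 and 0.53 and quartiles of -0.52 to 1.21 and -0.23 to 1.45.

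Many Drop-seq barcodes lay 1 base from another: 21 pairs in A and 6 in B. Barcodes alike by chance are argued against, since 0 of 10000 sets of random barcodes per library held as many pairs. Such pairs correlated in expression more than other pairs, with a mean of 0.0895 against -0.0272 in A and 0.077 against -0.0312 in B, and a permutation of the cells reached this with a share of 1e-05 in each, the smallest it can give. A candidate explanation is that 1 bead was read under several barcodes, which would leave 25 and 28 cells. Cells of SCRB-seq B with designed barcodes 1 base apart also correlated more (0.00987 against -0.0232, share 0.00012), as did those of CEL-seq2 A (-0.0161 against -0.0307, share 0.0279) and MARS-seq A (-0.0051 against -0.0358, share 0.0463) but not of CEL-seq2 B (share 0.598), MARS-seq B (0.378) or SCRB-seq A (0.201), so other sources of likeness stay open, and no biological explanation was tested.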

How the results depend on the processing

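Protein-coding genes alone, genes with 10 counts in every library and joined Drop-seq barcodes were chosen only after the results were seen. The others were fixed before the data were examined. Values of the results under alternatives numbered 266. Of these, 199 kept their side of the threshold or stayed within 1.5 times, 16 no longer passed, 2 newly passed and 49 moved further. They were counts of calls or p-values without direction, so no reversal could be recorded among them. Of 10284 values for named genes under alternatives, 9453 held, 588 no longer passed, 242 newly passed and 1 reversed: Lgals1 in full-length against 3' tag methods under limma on mean log2(CPM + 1) over cells (0.042, adjusted p = 0.933). Unless a cause is given, the cause was not tested. Numbers after a contrast are genes called, unless a p or share is named.

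DESeq2 size factors gave 325 for Drop-seq against SCRB-seq. No filter on low counts gave 469 for Drop-seq against SCRB-seq. Cells thinned to 10000 counts, with fewer genes tested, gave 3982 for full-length against 3' tag methods and 1177 for C1 difference between chemistries. glmTreat, which asks for more than a 2-fold change, gave 3350 for full-length against 3' tag methods, 671 for Smart-seq / C1 against Smart-seq2, 768 for in vitro transcription against PCR tag methods, 1699 for CEL-seq2 against MARS-seq, 29 for Drop-seq against SCRB-seq and 1297 for C1 difference between chemistries. limma on mean log2(CPM + 1) over cells gave 6427 for CEL-seq2 against MARS-seq, 3977 for Drop-seq against SCRB-seq and 6485 for C1 difference between chemistries. The DESeq2 Wald test gave 954 for Drop-seq against SCRB-seq. Protein-coding genes without ribosomal protein, histone, mitochondrial and Gm genes, a smaller set, gave 3631 for full-length against 3' tag methods, 2044 for in vitro transcription against PCR tag methods, 1676 for CEL-seq2 against MARS-seq, 126 for Drop-seq against SCRB-seq and 1336 for C1 difference between chemistries. Genes with 10 counts in every library, a smaller set, gave 2551 for full-length against 3' tag methods, 1490 for in vitro transcription against PCR tag methods, 1586 for CEL-seq2 against MARS-seq and 1284 for C1 difference between chemistries. Camera with an estimated correlation gave 0 for gene lists. The exact permutation p with the median over cells was 0.0734 for pluripotency genes detected at 10000 counts. With cells thinned to 5000 counts there was an exact permutation p of 0.0956 for pluripotency genes detected at 10000 counts and 25 for genes variable among cells across methods. A mean of at least 1 count gave 36 for genes variable among cells across methods. Under limma on the mean the share of higher calls went from 52.4% to 69.9% for full-length against 3' tag methods, 56.2% to 12.2% for Smart-seq / C1 against Smart-seq2, 46.96% to 81.1% for CEL-seq2 against MARS-seq, 68.1% to 11.5% for Drop-seq against SCRB-seq and 54.6% to 13.1% for the C1 difference. That alternative does not match depth between cells. Apart from the C1 difference, each of these shares moved towards the side with more counts per cell, but depth was not tested as the cause. In gene lists fry, which does not compare a list with other genes, called 52, and camera with an estimated correlation had 8 tests at an unadjusted p under 0.05. For full-length against 3' tag methods, called genes beyond 2-fold numbered 4343 after removing the length trend, against 5632 before.

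Leaving out 1 library at a time gave 6268 to 8012 genes for full-length against 3' tag, 614 to 3304 for Smart-seq / C1 against Smart-seq2, 1910 to 3974 for in vitro transcription against PCR, 1936 to 4053 for CEL-seq2 against MARS-seq, 8 to 676 for Drop-seq against SCRB-seq, 1121 to 2968 for the C1 difference and 32 to 103 variable genes. The exact permutation p ranged over 0.000481 to 0.0137 for genes per cell, 0.000962 to 0.0329 at 10000 counts, 0.00077 to 0.0961 for the mitochondrial share, 0.000192 to 0.00106 for the ribosomal protein share, 9.62e-05 to 0.365 for the spike-in share, 0.0155 to 0.0614 for pluripotency genes, 0.00298 to 0.0148 for extra-Poisson variation and 9.62e-05 to 0.000192 for the rank correlation, where the lowest is the smallest 10395 divisions can give.

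Replicate letters did not pair the libraries: differences A less B correlated between methods from -0.0839 to 0.0781, with 0 of 15 pairs above 0.1. With a replicate block the calls were 6815 for full-length against 3' tag methods, 2074 for Smart-seq / C1 against Smart-seq2, 2961 for in vitro transcription against PCR tag methods, 3169 for CEL-seq2 against MARS-seq, 183 for Drop-seq against SCRB-seq and 2063 for the C1 difference between chemistries. It gave 36 calls for gene lists and 75 genes variable among cells across methods. None of these counts moved by over 1.5 times. The p53 list in the C1 difference went from an adjusted p of 0.0489 to 0.0563, and the list of all mitochondrially encoded genes there from 0.0577 to 0.0396.

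Depth limits the results: at 20000 counts 9 and 7 MARS-seq cells and 23 and 27 Drop-seq barcodes had to be left out. Library totals ran from 583302 to 34984056 counts.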

Other observations

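No hypothesis is tested here, and these values were chosen only after they were seen. Zscan4 genes, markers of the rare 2-cell-like state, were counted in 30 of 39 thinned cells of SCRB-seq A (60.7 to 88.9%) and 6 of 45 of B. They had 630 UMIs in A and 58 in B, and 2 cells held 49.7% of those in A. Slc34a2 was counted in every Smart-seq2 cell, with a median of 11733 CPM in A and 14998 CPM in B, and in no other library did the median cell exceed 88.7 CPM. Xist, the RNA that silences an X chromosome, was counted in 48 of 69 thinned cells of Smart-seq / C1 A and 20 of 61 of B. Among the other libraries the share was highest in SCRB-seq B, with 13 of 45 thinned cells. Without thinning Xist was counted in 68 and 47 cells of Smart-seq / C1 A and B. In Smart-seq2 A and B it was then counted in 49 of 80 and 51 of 77. In Drop-seq A, joining barcodes 1 base apart moved the median count of mouse genes per cell from 18882 to 38109, and in B from 16188 to 17102.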
